A study of Pseudomonas putida KT2440 with 21 samples.

How the data were processed

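The data are RNA counts from 21 libraries of Pseudomonas putida KT2440, in 7 groups of 3 biological replicates: a control taken just before addition, and NaCl, hydrogen peroxide (H2O2) or imipenem at 7 and 60 min. Per the labels' protocols, RNA was extracted with Trizol and treated with DNase I, rRNA was depleted with Ribo-Zero for Gram-negative bacteria, and libraries were made with a TruSeq Stranded mRNA kit and sequenced as single reads of 100 bp on a HiSeq 2000. Per the submitters' processing notes, reads were trimmed with Trimmomatic, with no version given. The table the authors deposited holds a raw count per feature and library, and those count columns were used as deposited. The aligner, the counting tool and their treatment of reads with several matches are not given in the sources used here, so values of multi-copy features (rRNA operons, vgrG copies and repeated small RNAs) are uncertain. The deposited annotation gives a KT2440 chromosome of 6181863 bp, and coordinates are as it lists them. The table also holds 132 columns that name libraries outside this series, and these were left out.

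The table lists 6646 features: 5350 annotated genes, of which 1411 have a symbol, 250 intergenic small RNAs, 218 antisense RNAs and 828 predicted RNAs. Of these, 108 were set aside, 20 at rRNA loci, 54 antisense to rRNA loci and 34 at tRNA loci, which left 6538. Filtering by edgeR's filterByExpr with the groups left 6093. Genes without a symbol are named by their locus tag. Symbols come from the deposited files alone, since the reference table of gene names describes another assembly without these tags.

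Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood model with a mean per group over all 21 libraries and no covariate. Each of 15 comparisons (6 with the control, 3 of 60 with 7 min, and 6 between stresses at the same time) was a contrast in that fit. Features were called at a Benjamini-Hochberg adjusted p below 0.05 over all features of the comparison. The standard error is the size of the log2 fold change divided by the square root of the test's F. The common biological coefficient of variation was 0.257 and the prior degrees of freedom 6.59. Log2 CPM, used for the principal components and the gene lists, had a prior count of 2. A fold against a group at 0 in all libraries was taken against a floor of 3 counts over the group.

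The groups, tests, gene lists' topics and the rule for naming genes were chosen before the data were examined. Per comparison with the control, the named genes are the 8 largest increases and 8 largest decreases (4 each in the other comparisons) among genes with an adjusted p below 0.05, all 3 libraries beyond all 3 of the other group and a mean of at least 100 counts per library in the higher group. Added to these are up to 4 passing members and up to 2 opposite or failing members of each list described, and the genes rpoS, rpoH, algU, katA, ahpC, ahpF, recA, lexA-1, lexA-2, ampC and rpoD, while oxyR and katB were not found by symbol. For listed small RNAs, up to 3 passing changes each way are given in the comparisons with the control. By chance, 10% of features would have 3 libraries beyond 3 others in either direction.

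The 25 gene lists were filled by matching symbols and product names, which gave 853 matches, and 66 that did not belong by their product were removed by hand, leaving 787. Lists with at least 4 tested genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 375 tests. Camera with an estimated correlation and fry were run beside it, and members were also counted with adjustment over the list alone. Overlaps between stresses were set beside the number that independent lists would give and 20 simulations of unchanged groups against the same controls.

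The alternatives planned were DESeq2's size factors, DESeq2's Wald test (version 1.42.0), no filter, rRNA and tRNA features kept, the replicate number as a block, only the 2 groups compared, changes of at least 2-fold, an adjusted p below 0.01, and each library left out in turn. Chosen after seeing the data were 1 surrogate variable (sva 3.50.0), leaving out control replicate 1 and imipenem 60 min replicate 1 together, annotated genes only, and the gene lists as first matched. Figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

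The fit was tested on simulated data with 200 of 6093 features changed by known folds. At 4-fold it recovered 80.3% and 83.3% in NaCl 7 and 60 min, 78.8% and 87.9% in H2O2 and 81.8% and 77.3% in imipenem. At 2-fold, in the same order, it recovered 35.8%, 28.4%, 19.4%, 41.8%, 20.9% and 13.4%, and at 1.5-fold 1.5%, 3%, 1.5%, 6%, 7.5% and 4.5%. False calls were 3.2%, 2.1%, 3.7%, 6.6%, 6.5% and 1.3% of the calls. These rates hold only for such simulated data. Between replicates of a group, the chi-square per degree of freedom of the counts ran from 5.66 to 180, so replicates differ by more than counting noise. The kept count per library was from 991795 to 7887354, and 953 annotated genes had a count of 0 in imipenem 60 min replicate 1. No genome sequence was used here, so GC content was not checked.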

Results

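RNA was sequenced from cultures of Pseudomonas putida KT2440, a soil bacterium, grown in M9 glucose medium to an OD600 of about 0.6. NaCl at 3%, hydrogen peroxide (H2O2) at 0.05 mM or imipenem at 0.1 µg/mL was then added to 50 mL cultures. Imipenem is a beta-lactam antibiotic that blocks cell wall synthesis. Cells were taken 7 and 60 min after addition, and control cells just before it. Each of the 7 groups had 3 biological replicates, which makes 21 libraries. The total count per library, in the order of replicates 1 to 3, was 5317939, 10270091 and 10941547 in the controls, 7711747, 8536297 and 7723677 in NaCl 7 min, and 7677991, 8284459 and 6475325 in NaCl 60 min. It was 6861921, 3234852 and 3728904 in H2O2 7 min and 6273038, 12398543 and 11087474 in H2O2 60 min. It was 6512441, 7602611 and 5685439 in imipenem 7 min and 1354580, 3309016 and 2831014 in imipenem 60 min.

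Counts at rRNA and tRNA loci and antisense to rRNA were set aside, which left from 991795 counts (imipenem 60 min replicate 1) to 7887354 counts (control replicate 3) per library. Of these, a single RNA, the tmRNA, held from 12.2% (NaCl 60 min replicate 2) to 33.2% (H2O2 7 min replicate 2). In control replicate 1, 40.8% of the total count lay antisense to rRNA loci and 32.3% was kept. A total of 6093 features were tested, made up of 4983 annotated genes, 247 listed intergenic small RNAs, 141 listed antisense RNAs and 722 predicted RNAs. Values with ± are log2 fold changes with their standard errors from edgeR's quasi-likelihood test, with 3 libraries in each group, and adjusted p is that test's p after Benjamini-Hochberg adjustment over all features tested. Genes picked for the size of their change had all 3 libraries of 1 group beyond all 3 of the other. CPM is a library's counts scaled by its kept total and TMM factor, given as the mean of a group with its SD. Gene lists on topics chosen beforehand, with members matched by name and cleared by hand, were tested with camera at a preset correlation, and 78 of 375 tests passed after adjustment over all lists and comparisons. With a correlation estimated from the data, no list in any of the 15 comparisons passed camera (0 of 375, against 34 at an unadjusted p under 0.05, and 177 adjusted calls by fry). Each list that passed is therefore printed with its adjusted p under the estimated correlation. A surrogate variable is an estimated factor added to the fit. Control replicate 1 and imipenem 60 min replicate 1, left out together, are called the doubted pair, and both alternatives were chosen after seeing the data.

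**Figure D1:**
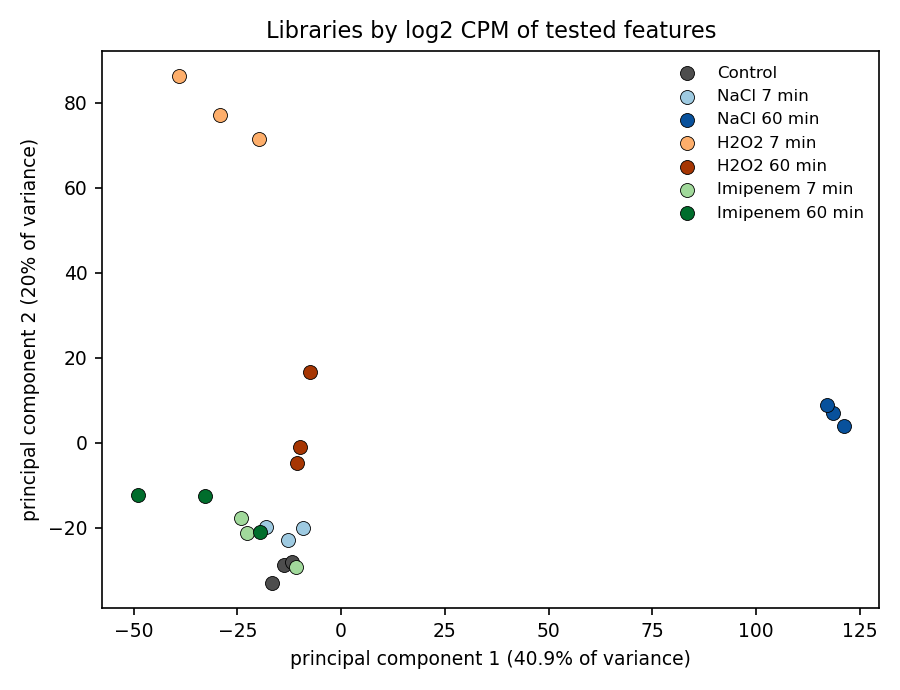
Each point is a library placed by the first and second principal components of log2 CPM, with the percent of variance on each axis and a colour per group. The NaCl 60 min libraries lie at 117 to 121 on the first component, against -48.99 to -7.56 for the other 18 libraries, and the H2O2 7 min libraries lie at 71.4 to 86.3 on the second.

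The comparisons with the control ask which transcripts osmotic, oxidative and cell envelope stress change early and late. All 6 share the same 3 control libraries. No untreated culture was sampled at 60 min, so the comparisons at 60 min hold the effect of 60 min of further culture as well as that of the compound.

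**Figure D2:**
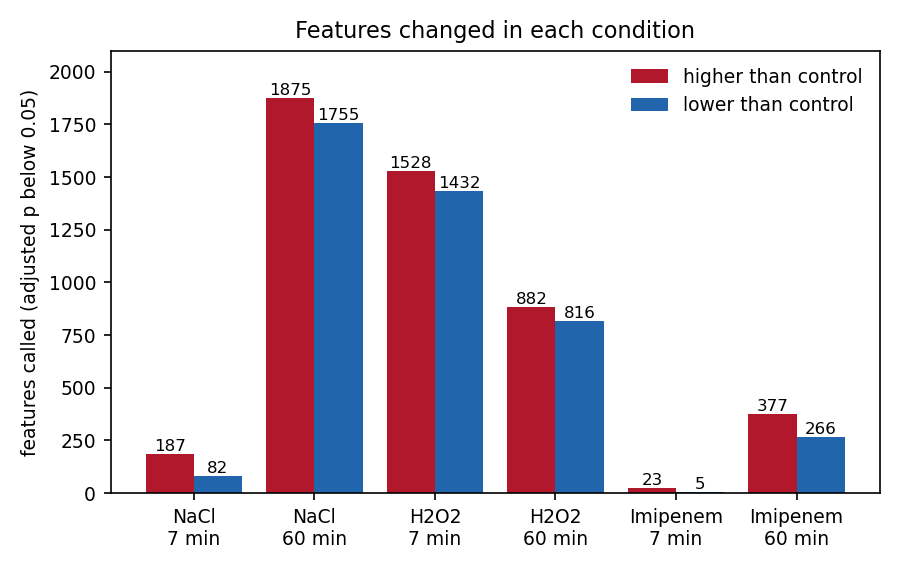
Bars give the number of features with an adjusted p below 0.05 in each condition against the control (3 libraries per group), with higher and lower features apart. The counts run from 23 higher and 5 lower in imipenem 7 min to 1875 higher and 1755 lower in NaCl 60 min.

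After 7 min of NaCl, the gene that rose most was the resolvase gene PP_1116, by 5.42 ± 0.44 (adjusted p 1.53e-07), from 30.5 ± 6.37 to 1290 ± 146 CPM. The hypothetical genes PP_3704 and PP_1833 rose by 4.11 ± 0.48 and 3.76 ± 0.43, the transport-associated gene PP_4707 by 3.08 ± 0.48 and the Cro/CI family regulator gene PP_0497 by 2.71 ± 0.23, all with adjusted p of 0.000525 or lower. PP_1149, PP_2629 and PP_2296 rose by 2.39, 2.37 and 2.22. Of the 36 compatible solute and osmoprotectant genes, the mechanosensitive channel gene mscL alone passed, at 1.27 ± 0.23 (adjusted p 0.0018; 273 against 113 CPM), and the set test on that list did not pass (adjusted p 0.7). The hypothetical gene PP_3921 fell by 1.98 ± 0.28 (adjusted p 0.000162). The quinoprotein ethanol dehydrogenase gene qedH fell by 2.82 ± 0.57 (adjusted p 0.00569), but not without control replicate 3 (0.12) or NaCl 7 min replicate 2 (0.0567) or with only the 2 groups fitted (0.161), and its control CPM of 16.2 had an SD of 18.4. Of the listed small RNAs, T61 rose by 4.79 ± 0.47, T33 by 3.93 ± 0.36 and Frameshift_16 by 3.39 ± 0.33, with adjusted p of 1.52e-06 or lower. PP5 fell by 1.15 ± 0.29 (adjusted p 0.0238), but not without control replicate 2 (0.146) or NaCl 7 min replicate 2 (0.146) or 3 (0.0644). The tmRNA held 26.7%, 26.0% and 22.0% of the kept counts in these libraries, against 16.9%, 18.1% and 13.4% in the controls.

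A total of 269 of the 6093 features changed after 7 min of NaCl, 187 higher and 82 lower, and 198 of them by at least 2-fold. With DESeq2's size factors the split was 214 higher and 54 lower. The count was 150, 126 and 115 without control replicate 1, 2 and 3, and 100 and 111 without NaCl 7 min replicate 1 and 2. It was 1162 with only the 2 groups fitted, 1102 with a surrogate variable and 437 with DESeq2's test. The 6 other decreases of largest size, in PP_2630, PP_2031, PP_1524, PP_0696, PP_1627 and PP_2628, had adjusted p from 0.0201 to 0.0498. Each failed without NaCl 7 min replicate 1 (0.109 to 0.234), NaCl 7 min replicate 2 (0.0687 to 0.18) or control replicate 2 (0.075 to 0.261). PP_2031, PP_1524 and PP_0696 also failed without control replicate 1 (up to 0.107) or 3 (up to 0.129) or NaCl 7 min replicate 3 (up to 0.11), PP_2628 without the first (0.0516) or last (0.0553) of these, and PP_1627 without control replicate 3 (0.0677). The flagellum and chemotaxis list was lower, with a median of -0.27 over 86 genes (camera adjusted p 0.00234; adjusted p 0.245 with an estimated correlation). Its 4 members that passed were flgK (-0.82), flgJ (-0.85), ctpL (-0.80) and cheA (-0.64), and adjusted over the list alone 7 passed. These 4 calls ended without control replicate 3 (adjusted p 0.0643 to 0.199), NaCl 7 min replicate 1 (0.0833 to 0.245) or NaCl 7 min replicate 2 (0.064 to 0.146), and all but flgK ended without control replicate 1 (up to 0.107) or 2 (up to 0.146). Those of ctpL and cheA ended without NaCl 7 min replicate 3 as well (0.136 and 0.0824).

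Other lists were lower after 7 min of NaCl by the set test, with small medians. The tRNA synthetase and translation factor list had a median of -0.34 over 34 genes (camera adjusted p 0.00456; adjusted p 0.888 with an estimated correlation). No member passed edgeR's test, 1 was higher and 5 lower at an unadjusted p under 0.05, DESeq2 called 1 higher and 2 lower, and adjusted over the list alone 1 was higher and 2 lower. Without the doubted pair the list did not pass (0.0536). The tricarboxylic acid and glyoxylate cycle list (26 genes, median -0.39) gave a camera adjusted p of 0.00698, with adjusted p 0.795 under an estimated correlation and 0.077 by camera without NaCl 7 min replicate 1. The list of glucose uptake and the Entner-Doudoroff pathway (29 genes, median -0.25) gave 0.0159, with adjusted p 0.568 under an estimated correlation and 0.0517 by camera without the same replicate or 0.062 as first matched. In edgeR's test neither list had a member that passed, against 5 and 3 lower at an unadjusted p under 0.05 and 0 and 1 called by DESeq2. The peptidoglycan list (35 genes, median -0.21) gave 0.0471, with adjusted p 0.888 under an estimated correlation. Its lower member, murB (-0.83, adjusted p 0.022; 1 also adjusted over the list alone), ended without control replicate 2 (0.0754) or 3 (0.119) or NaCl 7 min replicate 1 (0.0676) or 2 (0.141). The list did not pass without control replicate 1 (0.065) or 2 (0.137) or NaCl 7 min replicate 2 (0.0752) or 3 (0.0518), without the doubted pair (0.0536), with DESeq2's size factors (0.0826) or as first matched (0.0828).

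After 60 min of NaCl, 3 adjacent genes rose most or nearly so: PP_1748 by 9.85 ± 0.65, the acetyltransferase gene PP_1749 by 9.29 ± 0.72 and the asparagine synthetase gene asnB by 9.86 ± 0.80 (adjusted p 1.22e-09), which went from 7.08 ± 1.68 to 6870 ± 840 CPM. In the deposited annotation of the KT2440 chromosome, they span 1946552 to 1951442. PP_4707, already higher at 7 min, reached 9540 ± 826 CPM from 11.3 ± 3.72 (9.74 ± 0.63), and PP_3266, PP_1503, PP_1833 and PP_3241 rose by 9.27, 8.99, 8.64 and 8.43. Compatible solute genes were higher as a list, with 22 of 36 members higher and 7 lower (the same counts adjusted over the list alone), a median of 1.21 and a camera adjusted p of 0.000229 (adjusted p 0.407 with an estimated correlation). Its largest increases were in the glycine betaine transporter genes PP_0870 (8.38 ± 0.59) and PP_0868 (7.79 ± 0.46), osmC (7.78 ± 0.45) and the trehalose synthase gene PP_4059 (6.97 ± 0.30), and the mechanosensitive channel genes PP_0707 and PP_5256 fell by 1.48 and 1.41.

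The sigma factor gene algU rose by 3.99 ± 0.24 after 60 min of NaCl (adjusted p 2.06e-11), from 226 to 3600 CPM. The envelope stress and alginate list had 17 of 20 members higher, among them algD (5.85 ± 0.42), algE (5.78 ± 0.39), algK (5.67 ± 0.41) and algX (5.14 ± 0.43), while algW (-1.48) and algH (-0.84) were lower. Adjusted over the list alone the counts were again 17 and 2, and the median was 3.39 (camera adjusted p 4.6e-06; adjusted p 0.102 with an estimated correlation). The heat shock sigma factor gene rpoH rose by 2.48 ± 0.19, and 21 of 28 heat shock genes were higher (median 1.70, camera adjusted p 0.000194; adjusted p 0.352 with an estimated correlation). Of these, PP_3970 (a GroES family gene), clpB, ibpA and htpG rose by 5.93, 4.07, 3.62 and 3.22. The 3 lower members were PP_0680, hslR and, named after its value was seen, PP_4814, at -1.41, -0.97 and -0.96, and adjusted over the list alone the counts did not differ. By contrast rpoS fell by 1.35 ± 0.22 (adjusted p 2.53e-05).

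Of 86 flagellar genes, 47 were lower and 12 higher after 60 min of NaCl (48 and 12 adjusted over the list alone). The list's median was -0.60 and its camera adjusted p 0.000484 (adjusted p 0.171 with an estimated correlation). The largest decrease was in fliE, -2.87 ± 0.32, while the adjacent chemotaxis genes PP_3759 (CheB family) and PP_3760 (CheR family) rose by 5.49 each, and PP_1940 and chev-2 by 2.79 and 2.31. Cell division genes were higher in 14 of 20 cases (the same adjusted over the list alone), with a median of 0.84 (camera adjusted p 0.0266; adjusted p 0.202 with an estimated correlation). They were led by ftsK (2.24), minC (1.91), ftsA (1.90) and ftsX (1.72), and the lower member was PP_1328 (-1.19). Of 7 type VI secretion genes, 6 were higher (6 also adjusted over the list alone; median 2.60), with vgrG-3 at 5.63, vgrG-1 at 5.29 and hcp-1 at 3.60. That list passed camera (adjusted p 0.0416; adjusted p 0.797 with an estimated correlation), but not without NaCl 60 min replicate 3 (0.063), and reads may be split between vgrG copies. The catalase gene katE rose by 7.81 ± 0.41 and sodA by 2.57 ± 0.44, whereas tpx (-3.53 ± 0.25), trx-1 (-2.38 ± 0.21) and ahpC (-1.50 ± 0.24) fell. The peroxide and thiol list as a whole did not pass (median -0.81, adjusted p 0.0758).

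In total 3630 features changed after 60 min of NaCl, 1875 higher and 1755 lower, and 2947 by at least 2-fold. The largest decreases with enough counts were in the neighbouring genes PP_3783 (-4.11 ± 0.43), PP_3782 (-3.79), PP_3784 (-3.75), PP_3781 (-3.71) and PP_3785 (-3.42), followed by PP_4775 (-3.71) and the transporter gene PP_1016 (-3.47). Potassium transport genes did not pass as a list (median -0.64, adjusted p 0.173), although the antiporter gene PP_5066 and the TrkH family gene PP_3953 fell by 1.73 and 1.31, and kdpE and PP_4507 by 0.94 and 0.93. Among the remaining fixed genes, katA (1.54), recA (1.52), lexA-1 (1.19) and rpoD (0.93) rose and ampC fell by 0.94, each with an adjusted p of 0.0131 or lower, and lexA-2 did not pass (-0.52, adjusted p 0.27). A call on ahpF (-0.61, adjusted p 0.046) ended without control replicate 1 (0.0987) or 3 (0.177), without NaCl 60 min replicate 2 (0.105) or 3 (0.137), without the doubted pair (0.0811) and with DESeq2's size factors (0.151). The small RNAs 5'UTR-6, RNA30 and T89 rose by 7.12, 6.58 and 6.11, and P24 (-3.74), T91 (-3.66) and TPP_RS_2 (-3.14) fell. The median change of all features in this comparison was -0.05 with TMM, 0.12 with DESeq2's size factors and -0.15 with rRNA and tRNA counts kept.

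After 7 min of H2O2, the catalase gene katA rose by 9.61 ± 0.38 (adjusted p 1.73e-13), from 10.2 ± 1.88 to 8080 ± 2110 CPM. The alkyl hydroperoxide reductase genes ahpF and ahpC rose by 7.48 ± 0.31 (2540 against 14.3 CPM) and 6.12 ± 0.29 (5280 against 75.7 CPM), and the catalase/peroxidase gene PP_3668 by 4.82 ± 0.28. The Rieske family gene PP_5373 rose by 8.33 ± 0.45, PP_2309 by 8.08 ± 0.43, PP_2441 by 7.62 ± 0.42, PP_1834 by 6.85 ± 0.50, PP_0202 by 6.81 ± 0.31 and the thioesterase gene PP_4975 by 6.80 ± 0.40. Of 26 peroxide and thiol genes, 10 were higher and 5 lower (11 and 5 adjusted over the list alone), with a median of 0.53, and the set test did not pass (adjusted p 0.0711). The lower members were PP_1822 (-2.64), tpx (-1.69) and, named after their values were seen, PP_5054 (-1.34), PP_1235 (-1.22) and PP_1081 (-1.09).

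Some sulfur assimilation genes also rose after 7 min of H2O2, among them the sulfonate and taurine uptake genes ssuA (5.25 ± 0.38) and tauA (5.24 ± 0.28), the sulfate transporter gene cysP (5.12 ± 0.31) and ssuE (4.68 ± 0.35). Of 35 members 16 were higher and 5 lower (16 and 6 adjusted over the list alone), with a median of 0.59 (camera adjusted p 0.0338, but 0.0533 with the list as first matched; adjusted p 0.733 with an estimated correlation). The lower members included PP_4305 (-1.77), cysI (-1.76) and, named after their values were seen, cysM (-1.47) and cysNC (-1.37). In the SOS response and DNA repair list, dinP rose by 2.85 ± 0.27, lexA-1 by 2.29 ± 0.18, recN by 2.25 ± 0.22, recA by 1.89 ± 0.23 and uvrB by 1.49 ± 0.21. With 12 of 22 members lower, the list's median was -0.52 and its mean 0.09, and the set test, whose direction was down, did not pass (adjusted p 0.904). The sigma factor genes algU (1.34 ± 0.22) and rpoS (1.13 ± 0.22) rose, rpoD fell by 0.87 ± 0.24, ampC fell by 1.70 ± 0.33, and rpoH (-0.21, adjusted p 0.339) and lexA-2 (0.30, adjusted p 0.566) did not pass.

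Some translation genes fell after 7 min of H2O2. Of 34 tRNA synthetase and translation factor genes, 24 were lower (24 adjusted over the list alone), with a median of -1.25 (camera adjusted p 3.6e-06; adjusted p 0.733 with an estimated correlation). They included infA (-3.19 ± 0.55), glyQ (-2.60 ± 0.27) and lysS (-2.25 ± 0.25), and PP_0201 alone was higher (2.36 ± 0.28). Of 55 ribosomal protein genes, 21 were lower (21 adjusted over the list alone), with a median of -0.48 (camera adjusted p 0.0054; adjusted p 0.947 with an estimated correlation), and that call ended without H2O2 7 min replicate 1 (0.186). The largest changes were in rpsT (-3.43 ± 0.52), rpsU (-2.90), rpmF (-2.31) and rpmB (-2.30), and rpoX was higher (2.17 ± 0.42). Glutamate and proline genes were lower in 8 of 12 cases (9 adjusted over the list alone; median -0.93, camera adjusted p 0.0134; adjusted p 0.351 with an estimated correlation), including proC-2 (-1.96), proA (-1.56), gdhA (-1.37) and PP_1060 (-1.32). Peptidoglycan genes were lower in 15 of 35 cases (15 adjusted over the list alone; median -0.37, camera adjusted p 0.0266; adjusted p 0.888 with an estimated correlation), with mltD at -2.46 and mrdA-1 at -1.87, while dacA (1.62) and ddlA (1.13) were higher. Without H2O2 7 min replicate 2, that set call (0.0579) and the call on ddlA (0.058) ended, and the set call ended with a surrogate variable too (0.0584).

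In total 2960 features changed after 7 min of H2O2, 1528 higher and 1432 lower, and 2385 by at least 2-fold. Beyond the genes above, the largest decreases were in PP_1249 (-3.43 ± 0.41), PP_0007 (-3.31), the chorismate lyase gene PP_5317 (-3.30), trpB (-3.30), PP_1245 (-3.27) and sdaC (-3.17). Siderophore and iron uptake genes (12 of 43 higher, median 0.43, adjusted p 0.458) did not pass as a list, but PP_4606 and PP_0160 rose by 1.77 and 1.69 and PP_4137 fell by 2.01. Iron storage genes (9 tested, adjusted p 0.876) did not pass either, and PP_0482 rose by 1.14 while hscB and hscA fell by 0.94 and 0.91. The tmRNA held 16.5%, 33.2% and 30.5% of the kept counts in the H2O2 7 min libraries, against 13.4% to 18.1% in the controls. Listed small RNAs, whose median loading was -0.848 on an axis of spread between replicates on which the tmRNA share varied too (correlation -0.73), were higher in 96 of 247 cases and lower in 23, with 5'UTR-2 at 8.32, T71 at 7.42 and 5'UTR-13 at 7.36, against PP5 at -4.34, Frameshift_7 at -3.34 and Pseudomon-groES at -3.19.

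After 60 min of H2O2, the 8 genes that rose most all lay in the region from PP_2663 to PP_2682, between 3050166 and 3072308 on the chromosome. They were PP_2678 (6.63 ± 0.49, adjusted p 6.46e-09), PP_2675 (6.62 ± 0.56), PP_2663 (6.52 ± 0.54), qedH (6.50 ± 0.56), PP_2677 (6.48 ± 0.46), PP_2676 (6.40 ± 0.53), PP_2673 (6.28 ± 0.47) and PP_2669 (6.08 ± 0.50). All 19 tested genes of the region were higher, with a median of 5.85 (SD 1.14), and qedH rose from 16.2 ± 18.4 to 1580 ± 440 CPM. Of 26 peroxide and thiol genes 6 were higher and 8 lower (median -0.01), and the list did not pass (adjusted p 0.879). Above the control were katA by 2.74 ± 0.29, PP_3668 by 2.45 ± 0.26, ahpF by 1.67 ± 0.25, ohr by 1.23 ± 0.16 and ahpC by 1.11 ± 0.23, with adjusted p of 0.00122 or lower. The glutaredoxin gene PP_1822 fell by 1.89 ± 0.22. The repressor gene lexA-1 rose by 1.62 ± 0.18 (adjusted p 1.25e-06).

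Ribosomal protein genes were lower after 60 min of H2O2 in 39 of 55 cases (51 adjusted over the list alone), with a median of -1.28 (camera adjusted p 9.4e-16; adjusted p 0.733 with an estimated correlation). They included rpmH (-1.89 ± 0.26), rpsT (-1.84 ± 0.49), rplJ (-1.80 ± 0.42) and rplL (-1.66 ± 0.41). Of the tRNA synthetase and translation factor genes, 17 of 34 were lower (23 adjusted over the list alone; median -0.71, camera adjusted p 7.68e-06; adjusted p 0.733 with an estimated correlation). Among them glyS and glyQ were at -1.22 each, against PP_0201 at 1.90 and PP_4111 at 1.34. Glutamate and proline genes were lower in 8 of 12 cases (8 adjusted over the list alone; median -0.99, camera adjusted p 0.000215; adjusted p 0.121 with an estimated correlation), led by gltD and gltB (-1.53 each), glnA (-1.47) and gdhA (-1.33). Heat shock genes were lower in 13 of 28 cases (16 adjusted over the list alone; median -0.60, camera adjusted p 0.000997; adjusted p 0.438 with an estimated correlation), with hslV and hslU at -2.05 and htpG at -1.85. Their 5 higher members included PP_3312 (2.02) and PP_4814 (1.33), and, named after its value was seen, PP_3314 (1.02). Another was PP_3313 (1.26, adjusted p 0.0127), whose call ended without control replicate 2 (0.0834) or H2O2 60 min replicate 3 (0.052).

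Flagellar genes, in contrast to NaCl, were higher after 60 min of H2O2 in 27 of 86 cases (30 adjusted over the list alone), with a median of 0.46 (camera adjusted p 0.00262; adjusted p 0.245 with an estimated correlation). The largest increases were in PP_1228 (1.72), PP_3414 (1.65), flgA (1.47) and fliK (1.37). Compatible solute genes were higher in 16 of 36 cases and lower in 6 (17 and 7 adjusted over the list alone; median 0.69, camera adjusted p 0.00486; adjusted p 0.615 with an estimated correlation). They were led by glgX (2.40 ± 0.20), PP_4053 (2.24 ± 0.29), PP_2741 (2.12 ± 0.40) and PP_3558 (1.85 ± 0.22), and PP_1353 fell by 1.09. The largest decreases were in PP_0989 (-3.30 ± 0.26), PP_1400 (-2.75), bioB (-2.69), trpB (-2.67), PP_1249 (-2.57), accC-2 (-2.55), trpA (-2.53) and oadA (-2.46). The small RNAs RNA15, RNA21 and PP15 rose by 3.10, 2.92 and 2.89, and Pseudomon-groES and T58 fell by 2.12 and 1.61, while the call on T116/PP32 (-1.91, adjusted p 0.0036) ended without control replicate 2 (0.0544). In total 1698 features changed, 882 higher and 816 lower, and 1144 by at least 2-fold, against 1112 called without H2O2 60 min replicate 3 and 2669 with a surrogate variable. Calls on recA (0.66, adjusted p 0.0347) and lexA-2 (1.20, adjusted p 0.0268) ended without control replicate 3 (0.0853 and 0.0814), H2O2 60 min replicate 2 (0.0676 and 0.0542) or 3 (0.0652 and 0.117). That on recA also ended without control replicate 2 (0.135) or H2O2 60 min replicate 1 (0.0721), and that on lexA-2 without control replicate 1 (0.11). The other fixed genes did not pass: rpoS (0.33, adjusted p 0.282), rpoH (-0.45, 0.0664), algU (-0.03, 0.941), ampC (-0.72, 0.0842) and rpoD (-0.53, 0.102).

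After 7 min of imipenem, a few transport and lactate genes rose by large amounts. The L-lactate transport gene lctP rose by 7.39 ± 0.54 (adjusted p 1.1e-08), from 4.75 ± 0.849 to 772 ± 360 CPM, and the adjacent lactate dehydrogenase genes lldD and PP_4737 by 6.04 ± 0.33 and 6.09 ± 0.35. The C4-dicarboxylate transporter gene dctA rose by 6.02 ± 0.42 (586 against 9.9 CPM), the asparaginase gene ansA by 3.18 ± 0.43 and the glutamate/aspartate symporter gene gltP by 3.15 ± 0.27. The amino acid transporter genes PP_1069 and PP_1070 rose by 2.15 each, with adjusted p of 0.000493 or lower. In all, 28 features changed, 23 higher and 5 lower, and 26 by at least 2-fold, and the count was 124 without imipenem 7 min replicate 1, 50 with a surrogate variable and 60 with DESeq2's test. The flagellar gene fliF fell by 1.14 ± 0.17 (adjusted p 0.000493). The other 4 decreases were in flhF (-0.92, adjusted p 0.0406), fliH (-0.88, 0.0294), PP_0088 (-1.42, 0.024) and, named after its value was seen, the regulator gene PP_4273 (-2.23, 0.0359). Those of flhF, fliH and PP_0088 each ended without control replicate 2 (0.111 to 0.252) or 3 (0.128 to 0.207) or imipenem 7 min replicate 2 (0.163 to 0.264) or 3 (0.135 to 0.201), and that of flhF also without control replicate 1 (0.0712). That of PP_4273 ended without control replicate 1 (0.11), 2 (0.0968) or 3 (0.0618) or imipenem 7 min replicate 2 (0.264) or 3 (0.177), or without the doubted pair (0.112). With only the 2 groups fitted all 4 ended (0.0888 to 0.122).

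The flagellum and chemotaxis list was lower after 7 min of imipenem, with a median of -0.16 over 86 genes and 19 lower adjusted over the list alone, against 3 over all features (camera adjusted p 1.26e-05; adjusted p 0.102 with an estimated correlation). Ribosomal protein genes were higher by the set test (55 genes, median 0.37, camera adjusted p 0.000333; adjusted p 0.907 with an estimated correlation). With a surrogate variable the list did not pass (0.354), and the tmRNA held 12.5%, 26.9% and 25.0% of the kept counts in these libraries. EdgeR's test passed no member, 1 was higher at an unadjusted p under 0.05 and DESeq2 also called 0. Glutamate and proline genes (12 genes, median -0.40) had a camera adjusted p of 0.0143 (adjusted p 0.351 with an estimated correlation), but 0.0701 without control replicate 3. Adjusted over the list alone 2 members passed. Multidrug efflux genes (38 genes, median -0.23) had 0.0336 (adjusted p 0.795 with an estimated correlation), but 0.0651 without control replicate 1, 0.0724 without imipenem 7 min replicate 2, 0.0734 without the doubted pair and 0.251 with a surrogate variable. Glucose pathway genes (29 genes, median -0.20) had 0.0349 (adjusted p 0.638 with an estimated correlation), but 0.112, 0.104 and 0.074 without control replicate 1, control replicate 3 and imipenem 7 min replicate 2, 0.113 without the doubted pair and 0.0852 as first matched. Heat shock genes (28 genes, median -0.19; 4 lower adjusted over the list alone) had 0.0458 (adjusted p 0.736 with an estimated correlation), but 0.207, 0.0942 and 0.379 without control replicate 1, control replicate 3 and imipenem 7 min replicate 1, and 0.342 without the doubted pair. Peptidoglycan genes did not pass as a list (median -0.18, adjusted p 0.09). The beta-lactamase gene ampC (-0.37, adjusted p 0.581) did not pass, nor did rpoS (0.637), rpoH (0.942), algU (0.389), katA (0.77), ahpC (0.579), recA (0.495), lexA-1 (0.978), lexA-2 (0.493) or rpoD (0.451), with their adjusted p in brackets.

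After 60 min of imipenem, the genes that rose most were again those of the PP_2663 to PP_2682 region, and all 19 tested members were higher, with a median of 4.49 (SD 1.05). The largest changes were in qedH (5.54 ± 0.54, adjusted p 8e-07; 815 ± 131 CPM), the aldehyde dehydrogenase gene PP_2680 (5.39 ± 0.45), PP_2675 (5.34 ± 0.54), PP_2678 (5.25 ± 0.48), PP_2676 (5.20 ± 0.51), PP_2669 (4.94 ± 0.49), PP_2663 (4.89 ± 0.51) and PP_2677 (4.84 ± 0.44). Of the multidrug efflux genes, 4 of those that fell were PP_3455 (-2.18 ± 0.40, adjusted p 0.00363), PP_3456 (-1.92 ± 0.36, 0.00439), PP_3582 (-1.57 ± 0.35, 0.0146) and ttgB (-1.24 ± 0.25, 0.0098). That list had 6 of 38 members lower (6 adjusted over the list alone), with a median of -0.43 (camera adjusted p 0.0161; adjusted p 0.758 with an estimated correlation). It did not pass with a surrogate variable (0.0799) or without the doubted pair (0.0575). The calls on PP_3582 and ttgB ended without imipenem 60 min replicate 1 (0.0589 and 0.0651), that on PP_3582 without replicate 2 (0.0543), and that on PP_3456 without the doubted pair (0.0719). The beta-lactamase gene ampC did not pass (-0.66, adjusted p 0.167).

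In total 643 features changed after 60 min of imipenem, 377 higher and 266 lower, and 495 by at least 2-fold. With DESeq2's size factors the split was 425 higher and 167 lower. The count was 88, 81 and 117 without control replicate 1, 2 and 3, 56 and 104 without imipenem 60 min replicate 1 and 2, and 1986 without replicate 3. It was 41 with only the 2 groups fitted, 40 without the doubted pair, 156 with a surrogate variable and 1123 with DESeq2's test. Peptidoglycan genes were lower (35 genes, median -0.41, camera adjusted p 0.00486; adjusted p 0.815 with an estimated correlation), with 4 lower, mltD, murI, mrcB and mrdA-2, and 5 adjusted over the list alone. SOS genes were lower (22 genes, median -0.53, camera adjusted p 0.0276; adjusted p 0.795 with an estimated correlation), with 3 lower, recX, recG and lexA-1, and 6 adjusted over the list alone. All 7 of these calls ended without control replicate 1 (0.0551 to 0.0883), control replicate 2 (0.068 to 0.17) or imipenem 60 min replicate 1 (0.13 to 0.226). Those other than mltD ended also without control replicate 3 (0.0705 to 0.117) or imipenem 60 min replicate 2 (0.0937 to 0.176). The small RNAs RNA1 and RNA67 (2.37 and 2.11) passed, at adjusted p 0.00692 and 0.0101, but not without imipenem 60 min replicate 1 (0.0651 and 0.105), and RNA67 not without control replicate 2 (0.0506). Calls on T79 (2.70, adjusted p 0.0193) and Alpha_RBS (-0.98, 0.0497) ended without control replicate 1 (0.0587 and 0.0763), 2 (0.0739 and 0.12) or 3 (0.0705 and 0.114) or imipenem 60 min replicate 1 (0.178 and 0.226), that on Alpha_RBS also without replicate 2 (0.175), and both with a surrogate variable (0.114 and 0.0975). The tmRNA held 25.9%, 23.7% and 18.1% of the kept counts in these libraries.

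Ribosomal protein genes were higher after 60 min of imipenem by the set test (55 genes, median 0.37, camera adjusted p 0.00183; adjusted p 0.921 with an estimated correlation), but not without imipenem 60 min replicate 1 (0.134), without the doubted pair (0.0577) or with a surrogate variable (0.0751). Type VI secretion genes (7 genes, median 1.31) had a camera adjusted p of 0.0268 (adjusted p 0.772 with an estimated correlation), but 0.0561 without control replicate 1, 0.332 without imipenem 60 min replicate 1, 0.529 without the doubted pair and 0.207 with a surrogate variable. In edgeR's test neither list had a member that passed, against 12 and 3 higher at an unadjusted p under 0.05 and 3 and 1 called higher by DESeq2. Heat shock genes (28 genes, median 0.31) had 0.0283 (adjusted p 0.733 with an estimated correlation), but 0.108 without control replicate 2 and 0.0746 without imipenem 60 min replicate 2. Of its members PP_3313 (1.36), ibpA (0.80) and clpB (0.69) were higher and htpX (-0.80) lower, and 8 were higher and 2 lower adjusted over the list alone. These 4 calls ended without control replicate 1 (0.0625 to 0.0758), 2 (0.0994 to 0.13) or 3 (0.0808 to 0.122) or imipenem 60 min replicate 1 (0.169 to 0.208) or 2 (0.0931 to 0.144). The next largest decreases were in PP_1354, PP_1274, PP_1440, PP_0566, PP_1489 and PP_0673, from -2.18 to -1.67, with adjusted p from 0.0109 to 0.0495. Each ended without imipenem 60 min replicate 1 (0.0647 to 0.187) or 2 (0.0591 to 0.182), 5 of them without control replicate 2 (0.0541 to 0.111), and 4 without control replicate 1 (0.0601 to 0.0824) or 3 (0.0705 to 0.094). The genes rpoS (0.51, adjusted p 0.117), rpoH (0.25, 0.343), algU (0.35, 0.264), katA (0.51, 0.275), ahpC (0.49, 0.155), ahpF (0.14, 0.745), recA (0.19, 0.59), lexA-2 (-1.17, 0.088) and rpoD (0.32, 0.343) did not pass.

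**Figure D3:**
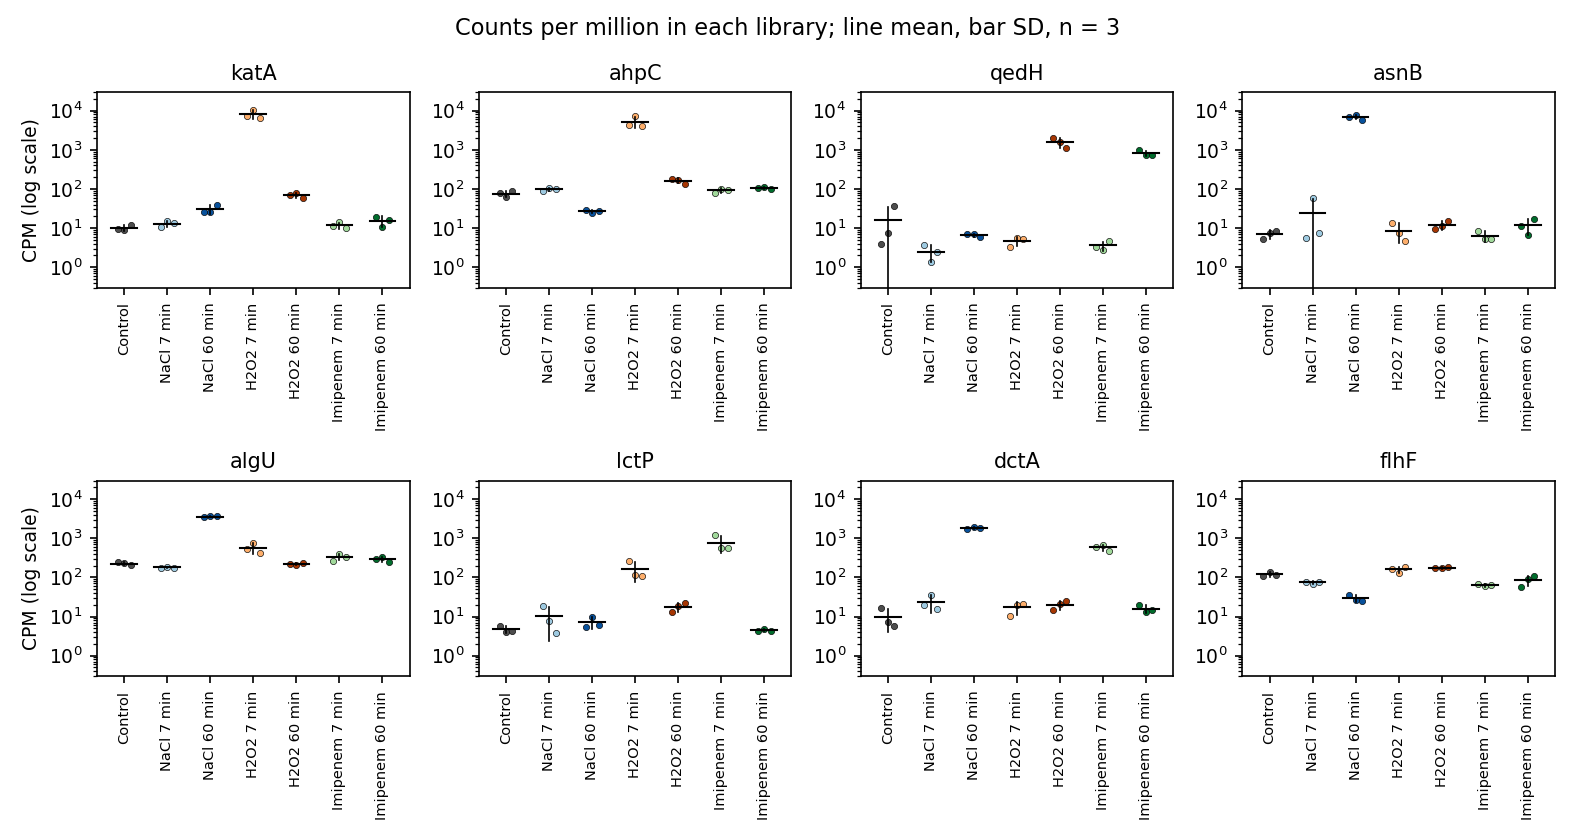
Points give the CPM of 8 genes in each library on a log axis, with a line at the mean and a bar of 1 SD for each group of 3 libraries; the bars are clipped at the lower edge of the axis. The gene katA is highest at 7 min of H2O2 (8080 CPM), asnB at 60 min of NaCl (6870 CPM), lctP at 7 min of imipenem (772 CPM) and qedH at 60 min of H2O2 (1580 CPM).

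The comparison of 60 with 7 min holds the effect of further culture as well as that of the compound. The controls enter only through the fit. In this and the next comparisons, counts of list members adjusted over the list alone were the same unless given. In NaCl, 3640 features differed, 1923 higher and 1717 lower at 60 min. The largest increases were in asnB (8.13 ± 0.74), PP_4061 (8.08 ± 0.61), PP_1748 (8.04 ± 0.59) and PP_1749 (7.80 ± 0.67). The largest decreases were in PP_0985 (-4.70 ± 0.49), PP_4248 (-4.50 ± 0.37), PP_3004 (-4.38 ± 0.49) and PP_3782 (-3.93 ± 0.49), and all 8 had an adjusted p of 6.7e-07 or lower. The envelope stress and alginate list had a median of 3.31 (17 of 20 higher; camera adjusted p 3.91e-06; adjusted p 0.102 with an estimated correlation). Compatible solute genes had 1.41 (21 of 36 higher; camera adjusted p 0.000215; adjusted p 0.407 with an estimated correlation). Heat shock genes had 1.54 (18 of 28 higher; camera adjusted p 0.000245; adjusted p 0.375 with an estimated correlation). Cell division genes had 0.93 (12 of 20 higher; camera adjusted p 0.0143; adjusted p 0.151 with an estimated correlation). Flagellar genes had -0.50 (40 of 86 lower; camera adjusted p 0.0157; adjusted p 0.407 with an estimated correlation). The type VI list (2.53, 6 of 7 higher; camera adjusted p 0.0376; adjusted p 0.795 with an estimated correlation) did not pass without NaCl 60 min replicate 3 (0.0608).

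In H2O2, 2588 features differed between 60 and 7 min, 1285 higher and 1303 lower at 60 min. The genes qedH (8.49 ± 0.65), PP_2673 (8.31 ± 0.61), PP_2677 (7.30 ± 0.52) and PP_2675 (7.22 ± 0.61) were higher. Lower were PP_5373 (-7.46 ± 0.42), PP_1742 (-7.06 ± 0.50), katA (-6.87 ± 0.34) and PP_2773 (-6.46 ± 0.36), and all 8 passed with adjusted p of 6.98e-09 or lower. Peroxide genes were lower as a list (14 of 26 lower; median -0.65, camera adjusted p 0.00103; adjusted p 0.351 with an estimated correlation). Sulfur genes were lower too (17 of 35 lower; median -0.60, camera adjusted p 0.00282; adjusted p 0.438 with an estimated correlation). Flagellar genes were higher (39 of 86 higher; median 0.49, camera adjusted p 0.0161; adjusted p 0.407 with an estimated correlation), but not without H2O2 7 min replicate 1 (0.0502). Ribosomal protein genes were lower (20 of 55 lower; median -0.62, camera adjusted p 0.0161; adjusted p 0.955 with an estimated correlation), but not without H2O2 7 min replicate 2 (0.243) or H2O2 60 min replicate 3 (0.445) or with a surrogate variable (0.197). The tRNA synthetase list was higher (17 of 34 higher, 19 adjusted over the list alone; median 0.64, camera adjusted p 0.0184; adjusted p 0.888 with an estimated correlation), but not without H2O2 7 min replicate 1 (0.0921) or H2O2 60 min replicate 1 (0.133). Compatible solute genes (15 of 36 higher; median 0.50, camera adjusted p 0.0458; adjusted p 0.772 with an estimated correlation) did not pass without H2O2 7 min replicate 1 (0.0595) or 2 (0.0527) or H2O2 60 min replicate 3 (0.0877) or with a surrogate variable (0.081). Heat shock genes (9 of 28 lower; median -0.35, camera adjusted p 0.0458; adjusted p 0.736 with an estimated correlation) did not pass without H2O2 7 min replicate 2 (0.0522) or 3 (0.0594) or H2O2 60 min replicate 2 (0.0551) or 3 (0.0532). Nor did they with a surrogate variable (0.0604), without the doubted pair (0.0595) or as first matched (0.0533).

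In imipenem, 76 features differed between 60 and 7 min, 47 higher and 29 lower at 60 min, and 393 without imipenem 60 min replicate 3. The count was 39 with only the 2 groups fitted, 216 with a surrogate variable and 175 with DESeq2's test. The genes qedH (7.83 ± 0.62), PP_2678 (7.50 ± 0.60), PP_2675 (7.20 ± 0.62) and PP_2676 (6.63 ± 0.56) were higher. Lower were lctP (-7.42 ± 0.59), lldD (-6.57 ± 0.39), PP_4737 (-6.32 ± 0.39) and dctA (-5.25 ± 0.42), and all 8 passed with adjusted p of 5.92e-08 or lower. Flagellar genes were higher (8 of 86 higher, 12 adjusted over the list alone; median 0.33, camera adjusted p 2.07e-06; adjusted p 0.102 with an estimated correlation), including fliF (1.24 ± 0.17). Heat shock genes were higher (28 genes, median 0.40, camera adjusted p 3.21e-06; adjusted p 0.174 with an estimated correlation), with 3 members over all features, clpB (1.14), ibpA (1.11) and, named after its value was seen, lon-1 (0.93), and 11 adjusted over the list alone. With only the 2 groups fitted these 3 calls ended (0.0557, 0.0971 and 0.131). Those on ibpA (0.177) and lon-1 (0.06) ended without the doubted pair, and that on ibpA without imipenem 7 min replicate 1 (0.131) or 3 (0.119) or 60 min replicate 1 (0.135) or 2 (0.0792). Peptidoglycan genes were lower by the set test (median -0.30, camera adjusted p 0.0346; adjusted p 0.888 with an estimated correlation), but not without imipenem 7 min replicate 1 (0.314), imipenem 60 min replicate 1 (0.274) or the doubted pair (0.283). Nor did the list pass with DESeq2's size factors (0.0666) or a surrogate variable (0.0604). No member of that list passed edgeR's test, against 10 lower at an unadjusted p under 0.05 and 0 called by DESeq2.

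The stresses were also compared with each other at each time, in the same fit of all 21 libraries. At 7 min, NaCl and H2O2 differed in 2761 features, 1303 higher in NaCl and 1458 lower, with infA (4.96 ± 0.59) and rpsT (4.54 ± 0.55) higher in NaCl and katA (-9.27 ± 0.37) and PP_5373 (-8.11 ± 0.45) lower. The tRNA synthetase list (median 0.89, 22 of 34 higher, 23 adjusted over the list alone; camera adjusted p 0.000156; adjusted p 0.788 with an estimated correlation) was higher in NaCl. So was the ribosomal list (0.34, 15 of 55 higher; camera adjusted p 0.0278; adjusted p 0.955 with an estimated correlation), but not without H2O2 7 min replicate 1 (0.426). Sulfur genes were lower (-0.52, 17 of 35 lower; camera adjusted p 0.0143; adjusted p 0.608 with an estimated correlation). Glutamate genes were higher (0.66, 7 of 12 higher; camera adjusted p 0.0498; adjusted p 0.551 with an estimated correlation), a call that ended without any of NaCl 7 min replicate 2 (0.0607) or 3 (0.0841) or H2O2 7 min replicate 1 (0.0566), 2 (0.0506) or 3 (0.0604), without the doubted pair (0.052) or with a surrogate variable (0.0515). H2O2 and imipenem differed in 2791 features, 1424 higher in H2O2 and 1367 lower, with katA (9.43 ± 0.38) and PP_5373 (8.90 ± 0.47) higher and dctA (-5.13 ± 0.41) and PP_2219 (-5.10 ± 0.78) lower. The tRNA synthetase list (median -1.40, 27 of 34 lower; camera adjusted p 2.68e-08; adjusted p 0.608 with an estimated correlation) was lower in H2O2. So was the ribosomal list (-0.91, 27 of 55 lower; camera adjusted p 1.43e-05; adjusted p 0.888 with an estimated correlation). Sulfur genes were higher (0.99, 18 of 35 higher, 20 adjusted over the list alone; camera adjusted p 0.0141; adjusted p 0.608 with an estimated correlation).

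At 7 min, NaCl and imipenem differed in 325 features, 164 higher in NaCl and 161 lower, against 178 and 112 with DESeq2's size factors. The count was 106 and 133 without NaCl 7 min replicate 1 and 2, and 161 and 146 without imipenem 7 min replicate 2 and 3. It was 829 with a surrogate variable and 488 with DESeq2's test. PP_1116 (5.12 ± 0.43) and PP_1833 (3.69 ± 0.43) were higher in NaCl, and lldD (-6.42 ± 0.34), lctP (-6.28 ± 0.51), PP_4737 (-6.17 ± 0.35) and dctA (-4.62 ± 0.39) lower. The tRNA synthetase list (median -0.48, camera adjusted p 7.68e-06; adjusted p 0.733 with an estimated correlation; 5 lower adjusted over the list alone) was lower in NaCl. So were the tricarboxylic acid cycle list (-0.46, 4.93e-05; adjusted p 0.608 with an estimated correlation) and the ribosomal list (-0.55, 0.000662; adjusted p 0.918 with an estimated correlation), the last not without imipenem 7 min replicate 2 (0.0589) or with a surrogate variable (0.982). Heat shock genes were higher (0.32, 0.0399; adjusted p 0.736 with an estimated correlation; 6 higher and 1 lower adjusted over the list alone), but not without NaCl 7 min replicate 2 (0.1) or 3 (0.0629), imipenem 7 min replicate 1 (0.191) or the doubted pair (0.0734), or with no filter (0.0606).

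At 60 min, NaCl and H2O2 differed in 3712 features, 1885 higher in NaCl and 1827 lower, with asnB (9.14 ± 0.77) and PP_4707 (9.02 ± 0.61) higher and PP_2673 (-9.57 ± 0.63) and PP_2681 (-8.50 ± 0.60) lower. Ribosomal protein genes had a median of 1.88 (42 of 55 higher; camera adjusted p 4.23e-06; adjusted p 0.888 with an estimated correlation). The envelope stress list had 2.82 (17 of 20 higher; 1.04e-05; adjusted p 0.12 with an estimated correlation). Heat shock genes had 1.81 (19 of 28 higher; 2.01e-05; adjusted p 0.245 with an estimated correlation). Flagellar genes had -1.02 (52 of 86 lower; camera adjusted p 7.68e-06; adjusted p 0.102 with an estimated correlation). Cell division genes had 1.17 (17 of 20 higher; 0.00235; adjusted p 0.102 with an estimated correlation). Compatible solute genes had 1.30 (19 of 36 higher, 21 adjusted over the list alone; 0.00865; adjusted p 0.679 with an estimated correlation). The tRNA synthetase list (0.75, 19 of 34 higher; camera adjusted p 0.0336; adjusted p 0.907 with an estimated correlation) did not pass without NaCl 60 min replicate 3 (0.0723) or H2O2 60 min replicate 3 (0.122), with a surrogate variable (0.0526) or as first matched (0.054).

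NaCl and imipenem differed at 60 min in 3520 features, 1858 higher in NaCl and 1662 lower, with asnB (9.21 ± 0.79) and PP_1748 (8.96 ± 0.66) higher and qedH (-6.95 ± 0.59) and PP_2669 (-6.68 ± 0.57) lower. PP_2707, listed at 0 in all 3 imipenem 60 min libraries, was at least 29.2-fold higher in NaCl, taking 3 counts over that group as the floor. The envelope stress list (median 3.11, 16 of 20 higher; camera adjusted p 4.43e-05; adjusted p 0.139 with an estimated correlation) was higher in NaCl. So were compatible solute genes (1.41, 22 of 36 higher; 0.000349; adjusted p 0.438 with an estimated correlation) and heat shock genes (1.10, 18 of 28 higher, 19 adjusted over the list alone; 0.00698; adjusted p 0.608 with an estimated correlation). Flagellar genes were lower (-0.76, 48 of 86 lower; 0.000194; adjusted p 0.139 with an estimated correlation). Peptidoglycan genes were higher (0.90, 22 of 35 higher, 24 adjusted over the list alone; 0.0471; adjusted p 0.888 with an estimated correlation), but not without NaCl 60 min replicate 1 (0.0516) or 3 (0.0557) or imipenem 60 min replicate 1 (0.0868) or 2 (0.0535) or the doubted pair (0.0992). Nor did they pass with a surrogate variable (0.0604) or as first matched (0.054).

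H2O2 and imipenem differed at 60 min in 2031 features, 1000 higher in H2O2 and 1031 lower, and in 1345 and 1279 without imipenem 60 min replicate 1 and 2. The count was 1009 with only the 2 groups fitted and 1253 without the doubted pair. PP_2575 (4.81 ± 0.62) and PP_3633 (4.70 ± 0.63) were higher in H2O2, and PP_1400 (-4.57 ± 0.30) and PP_1788 (-3.66 ± 0.68) lower, with adjusted p of 0.000608 or lower. Ribosomal protein genes were lower in H2O2 in 54 of 55 cases (54 adjusted over the list alone; median -1.64, camera adjusted p 7.79e-22; adjusted p 0.638 with an estimated correlation). Heat shock genes had -0.90 (16 of 28 lower; 1.26e-05; adjusted p 0.245 with an estimated correlation). The tRNA synthetase list had -0.65 (16 of 34 lower, 17 adjusted over the list alone; 0.000125; adjusted p 0.774 with an estimated correlation). SOS genes had 0.62 (10 of 22 higher, 12 adjusted over the list alone; 0.0104; adjusted p 0.736 with an estimated correlation), with lexA-1 at 2.32 ± 0.20. Compatible solute genes had 0.49 (13 of 36 higher; 0.0205; adjusted p 0.733 with an estimated correlation).

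**Figure D4:**
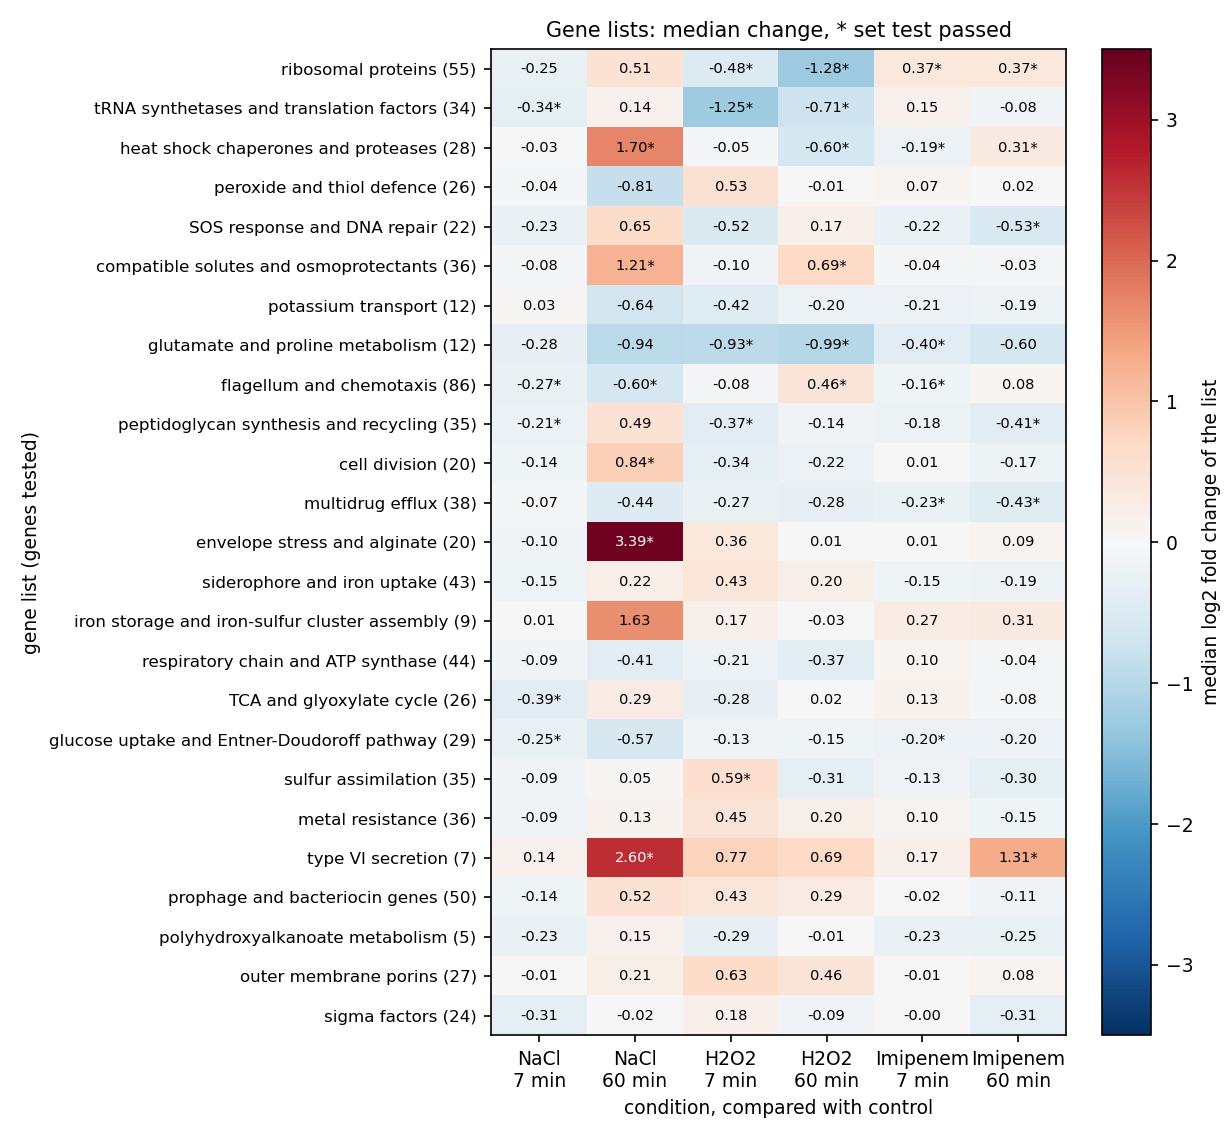
Each cell gives the median log2 fold change of a gene list (lines, with the number of genes tested) in a condition against the control (columns), coloured from blue for lower to red for higher, with a star where camera at its preset correlation passed. The largest median is that of the envelope stress and alginate list at 60 min of NaCl (3.39), and ribosomal proteins are lowest at 60 min of H2O2 (-1.28).

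At 7 min, NaCl and H2O2 changed 147 features in the same direction (95 higher, 52 lower) and 33 in opposite directions, against 46.9 and 19.3 for independent lists. In 20 simulations of unchanged groups against the same controls it was 0, which does not gauge what they add between changed groups. Without control replicate 1, 2 and 3 the 147 became 76, 64 and 57, and with a surrogate variable 569. H2O2 and imipenem shared 11 features at 7 min, all higher, against 5.8 for independent lists, and lctP (5.15 and 7.39), lldD (3.06 and 6.04) and PP_4737 (1.64 and 6.09) were among them. The 3 features called in opposite directions, named after their values were seen, were gltP (-0.66 and 3.15), PP_4273 (1.60 and -2.23) and the predicted RNA predRNA_144734_plus (-4.59 and 3.57). The H2O2 call on gltP ended without any 1 control (0.0818 to 0.0994) or H2O2 7 min library (0.062 to 0.124), that on predRNA_144734_plus without H2O2 7 min replicate 1 (0.074), and the imipenem call on PP_4273 as given above (up to 0.264). NaCl and imipenem shared dctA alone (1.40 and 6.02), also named after its values were seen, against 0.7 for independent lists, and the number was 0 to 2 without single controls. The NaCl call on dctA ended without control replicate 2 (0.177) or 3 (0.231) or NaCl 7 min replicate 1 (0.0737) or 2 (0.267), or with only the 2 groups fitted (0.0714). At 60 min, H2O2 and imipenem shared 229 features (124 higher, 105 lower, against 54.6 and 35.6 for independent lists) and 16 moved in opposite directions, and the shared increases included the PP_2663 to PP_2682 region. NaCl and H2O2 shared 763 (324 higher, 439 lower, against 271.4 and 235), with 325 opposite, and NaCl and imipenem 229 (98 higher, 131 lower, against 116 and 76.6), with 137 opposite. All 3 stresses shared 101 features at 60 min (36 higher, 65 lower, against 16.8 and 10.3). Without control replicate 1, 2 and 3 the count shared by H2O2 and imipenem was 54, 51 and 72, that by NaCl and imipenem 34, 25 and 47, and that by all 3 was 21, 17 and 32. Without the doubted pair these 3 counts were 36, 11 and 10, and with a surrogate variable 112, 63 and 51. The 3 controls are too few to be divided into sets of at least 2, so part of the excess may come from the shared controls.

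Of the 25 lists, 9 passed in no comparison by camera at the preset correlation. Their lowest adjusted p among the 15 comparisons were 0.173 for potassium transport, 0.211 for siderophores and iron uptake, 0.0959 for iron storage and iron-sulfur clusters, 0.09 for the respiratory chain and ATP synthase and 0.17 for metal resistance. They were 0.0576 for prophage and bacteriocin genes, 0.309 for polyhydroxyalkanoate metabolism, 0.324 for outer membrane porins and 0.0639 for sigma factors. At 60 min of NaCl, 18 of 50 prophage, 12 of 43 siderophore and 6 of 9 iron storage genes were higher. Of 44 respiratory chain genes 20 were lower. Of all 6093 features 1875 were higher and 1755 lower.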

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

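The tests of genomic DNA, depth, short RNAs, culture day and the PP_2663 to PP_2682 region below were chosen after the result was seen, while those of strand information and of other splits of the libraries were planned. Differences between 60 and 7 min were tested directly, and 3640, 2588 and 76 features differed in NaCl, H2O2 and imipenem. In NaCl 66 features passed in opposite directions at 7 and 60 min against the control, in H2O2 52 and in imipenem 0. For imipenem, edgeR's test of the difference between times gave 891 features at an unadjusted p under 0.05 and DESeq2 called 175.

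Gene lists stand out for a difference between the times by camera at its preset correlation, though none with an estimated correlation (0 of 375 tests). In NaCl the medians of 60 against 7 min were 1.544 for heat shock, 1.414 for compatible solutes, -0.496 for flagella, 0.929 for cell division, 3.308 for envelope stress and alginate and 2.526 for type VI secretion. In H2O2 they were -0.618 for ribosomal proteins, 0.635 for tRNA synthetases, -0.351 for heat shock, -0.649 for peroxide and thiol defence, 0.499 for compatible solutes, 0.495 for flagella and -0.605 for sulfur assimilation. In imipenem they were 0.398 for heat shock, 0.327 for flagella and -0.297 for peptidoglycan.

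Counts at rRNA loci, which no comparison uses, exceeded the highest control (35.9%) in NaCl 7 min replicate 1 (37.8%), imipenem 60 min replicate 3 (52.1%), H2O2 7 min replicate 1 (39.8%) and H2O2 7 min replicate 3 (39.6%). Counts at tRNA loci exceeded the highest control (1.29%) in NaCl 60 min replicate 2 (1.32%) and imipenem 7 min replicate 2 (1.38%).

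In control replicate 1, reads antisense to rRNA loci made up 40.8% of the total count. Loss of strand information in that library would raise antisense counts elsewhere too, but its share on antisense RNAs outside rRNA loci was 0.96 times that of the higher other control. Reads from genomic DNA would cover these loci in proportion to their length, but their share of the counts was 65.7 times their share of the chromosome. Both values argue against those explanations as the whole cause, and no biological explanation was tested.

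An axis common to several groups holds 51.9% of the spread between replicates. Unequal recovery of short RNAs may underlie it: the share of the tmRNA, as a deviation within groups, had a correlation of -0.73 with the axis (p 0.00092), and genes under 300 bp had a median loading of -0.347 (340 genes) against 0.322 for longer ones (4643 genes). Depth cannot be told apart from no effect with these libraries (correlation 0.26, p 0.352). Same-numbered libraries deviated in opposite ways in some pairs, with a lowest correlation of -0.58 and a highest of 0.72. Opposite pairs among 63 cannot exclude a shared culture day marked by the replicate number, so that question stays undecided. No biological explanation was tested.

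The 19 genes of the PP_2663 to PP_2682 region were higher at 60 min in H2O2 (median 5.85, SD 1.14) and imipenem (4.49, SD 1.05). An effect of 60 min of culture alone, whatever the compound, is argued against by the median of -1.28 (SD 1.07) in NaCl at 60 min. Growth over 60 min in cultures that kept growing could account for it and cannot be told apart from the compounds, because the number of untreated libraries taken at 60 min is 0. An effect of H2O2 and imipenem themselves stays open as well.

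For each comparison, the 6 libraries make 10 splits into 3 against 3, and 1 of the 10, the real split, gave as many calls in a fit of those libraries alone. With 10 splits the share cannot fall under 0.05. The real counts against the control were 1162 and 4170 in NaCl at 7 and 60 min, 2688 and 2135 in H2O2, and 22 and 41 in imipenem. Between 60 and 7 min they were 4121, 2131 and 39 in NaCl, H2O2 and imipenem. Between stresses at 7 min they were 2541 (NaCl and H2O2), 332 (NaCl and imipenem) and 2079 (H2O2 and imipenem), and at 60 min 4080, 2909 and 1009 in the same order. The highest count from another split was 1 in imipenem 7 min and 0 in the other 14 comparisons.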

How the results depend on the processing

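The surrogate variable, the removal of control replicate 1 with imipenem 60 min replicate 1, annotated genes only and the lists as first matched were chosen after the result was seen, and the other alternatives were planned. Of 490 results for named genes and small RNAs, none passing either fit changed direction. With 1 surrogate variable 446 kept their side of the threshold. So did 468 with DESeq2's test, 470 with its size factors and 454 without those libraries. With only the 2 groups fitted 434 of 482 did, 29 were weaker and 19 stronger. With the replicate number as a block 473 did and 15 were weaker, and over all fits without 1 library 2705 of 2940 values did and 208 were weaker. Where a value below moved, the cause was not tested. Some alternatives used fewer libraries, fewer features or a stricter threshold by construction. The pseudocount alternatives, meant for normalized values, were not run because the table holds counts.

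Leaving out 1 library gave, from lowest to highest, 100 to 228 changed features in NaCl 7 min (269 with all), 3269 to 3425 in NaCl 60 min (3630), 2603 to 2908 in H2O2 7 min (2960), 1112 to 1650 in H2O2 60 min (1698), 21 to 124 in imipenem 7 min (28) and 56 to 1986 in imipenem 60 min (643). It gave 3305 to 3377 (3640), 2094 to 2639 (2588) and 57 to 393 (76) between 60 and 7 min in NaCl, H2O2 and imipenem. At 7 min it gave 2391 to 2657 for NaCl against H2O2 (2761), 106 to 377 for NaCl against imipenem (325) and 2494 to 2669 for H2O2 against imipenem (2791), and at 60 min 3392 to 3604 (3712), 3085 to 3545 (3520) and 1279 to 2682 (2031). It gave 70 to 80 lists (78). The lowest and highest values beyond 1.5 times came without NaCl 7 min replicate 1 (100 and 106), H2O2 60 min replicate 3 (1112), imipenem 7 min replicate 1 (124), and imipenem 60 min replicate 1 (56), 2 (1279) and 3 (1986 and 393).

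With 1 surrogate variable the counts were 1102 in NaCl 7 min, 2669 in H2O2 60 min, 50 and 156 in imipenem 7 and 60 min, 216 between the imipenem times and 829 for NaCl against imipenem at 7 min. With DESeq2's test they were 437 in NaCl 7 min, 60 and 1123 in imipenem 7 and 60 min, 175 between the imipenem times and 488 for NaCl against imipenem at 7 min. With only the 2 groups fitted they were 1162 in NaCl 7 min, 41 in imipenem 60 min, 39 between the imipenem times and 1009 for H2O2 against imipenem at 60 min. At an adjusted p below 0.01 they were 103 in NaCl 7 min, 1021 in H2O2 60 min, 53 in imipenem 60 min, 112 for NaCl against imipenem at 7 min (216 at 2-fold or more) and 1169 for H2O2 against imipenem at 60 min. With annotated genes only they were 176 in NaCl 7 min and 419 in imipenem 60 min. Without control replicate 1 and imipenem 60 min replicate 1 they were 40 in imipenem 60 min and 1253 for H2O2 against imipenem at 60 min. Camera called 0 lists with an estimated correlation (34 of 375 at an unadjusted p under 0.05), also 0 with the surrogate variable added, and fry called 177. Of the 78 lists called, 64 still passed with the surrogate variable and 14 did not, 65 passed without those libraries together, 76 with DESeq2's size factors, 71 as first matched, 77 with no filter and 63 by fry.

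Overlaps at 7 min are given for NaCl with H2O2, NaCl with imipenem, H2O2 with imipenem, and all 3 (147, 1, 11 and 0 by edgeR), and at 60 min in the same order (763, 229, 229 and 101). Leaving out 1 control gave 57 to 76, 0 to 2, 9 to 11 and 0 to 2 at 7 min, and 540 to 571, 25 to 47, 51 to 72 and 17 to 32 at 60 min. With 1 surrogate variable they were 569, 7, 28 and 4 at 7 min, and 1314, 63, 112 and 51 at 60 min. With DESeq2's test they were 234, 8, 31 and 5 at 7 min, and 409 (NaCl with imipenem) and 152 (all 3) at 60 min. Without control replicate 1 and imipenem 60 min replicate 1 they were 97, 4 (NaCl with imipenem) and 3 (all 3) at 7 min, and 11, 36 and 10 in the last 3 at 60 min. At 2-fold or more they were 90 for NaCl with H2O2 at 7 min, and 428, 129, 148 and 44 at 60 min. With DESeq2's size factors they were 2 (NaCl with imipenem) and 1 (all 3) at 7 min.

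With the replicate number as a block, the counts were 222 in NaCl 7 min, 3568 in NaCl 60 min, 2892 in H2O2 7 min, 1614 in H2O2 60 min, 20 in imipenem 7 min, 467 in imipenem 60 min, and 3587, 2492 and 68 between the times, with 75 lists and an overlap of all 3 stresses of 1 at 7 min. Calls on PP_4273 in imipenem 7 min (0.0596), dctA in NaCl 7 min (0.0612) and gltP in H2O2 7 min (0.0643) ended with it. Correlations of deviations over 63 same-numbered pairs ran from -0.58 to 0.72 (mean -0.03), 18 were over 0.1, and 6 of 21 libraries correlated best with their own number. Between the 7 and 60 min libraries of the same stress and number they ran from -0.56 (imipenem replicate 1) to 0.23 (NaCl replicate 1). No pairing by number was detected, but such correlations cannot exclude one. The main fit treated these libraries as independent.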

Other observations

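Genes that lie side by side changed together in several conditions. At 60 min of NaCl, the neighbours PP_1748, PP_1749 and asnB rose by 9.85, 9.29 and 9.86, and the 5 neighbours PP_3781 to PP_3785 fell by 3.42 to 4.11. At 7 min of imipenem, lctP, lldD and PP_4737, which lie between 5383535 and 5389299, rose by 7.39, 6.04 and 6.09. These neighbours were noticed after the values were seen.

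Listed intergenic small RNAs were higher in 30 cases and lower in 1 in NaCl 7 min, 49 and 74 in NaCl 60 min, 96 and 23 in H2O2 7 min, 32 and 21 in H2O2 60 min, and 61 and 2 in imipenem 60 min. Their median loading was -0.848 on the axis of spread between replicates, on which the tmRNA share of kept counts varied too (correlation -0.73). That share, in replicates 1 to 3, was 16.9%, 18.1% and 13.4% in the controls, 26.7%, 26.0% and 22.0% in NaCl 7 min, and 12.9%, 12.2% and 14.4% in NaCl 60 min. It was 16.5%, 33.2% and 30.5% in H2O2 7 min, 17.9%, 16.0% and 18.1% in H2O2 60 min, 12.5%, 26.9% and 25.0% in imipenem 7 min, and 25.9%, 23.7% and 18.1% in imipenem 60 min.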
